A study of Mus musculus with 6 samples.

How the data were processed

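RNA-seq of bone marrow derived macrophages was analysed from 1 deposited table of 54232 genes with 6 library columns, 3 from SIRPa KO and 3 from WT cells. Groups and replicate numbers came from the sample titles. Per the submitters' processing notes, reads were processed with CASAVA 1.4, STAR 2.5.1b, featureCounts 1.6.0 and DESeq2 1.22.2 on GRCm38. Per the series' design text in the labels, the kit was stranded, read quality was examined with FastQC 0.10.1 and alignment used TopHat 2.0.10. The aligner is thus given in 2 ways, and which one made the table is not known. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical paralogs or pseudogenes may be split between them.

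The deposited library columns hold a signal, namely gene read counts that the authors divided by 1 size factor per library. Every positive value was a whole multiple of 1 step per library within 0.001 reads (100% of positive values), so whole reads were recovered. The mean column in the deposited table, also a normalized signal, equals the mean of the 6 libraries. Per the file headers, the authors' table also gives a log2 fold change with its standard error, a Wald statistic, which is a score without a fixed range, and a p-value with its adjusted p-value. Refitting DESeq2 1.42.0 to the recovered reads gave the authors' log2 fold changes within 6.37e-05. Of the IDs, 54079 were found in GENCODE M21, which gave coordinates and gene types on GRCm38, and 67 entries without a gene name, which held about 0.003% of reads, were kept under their IDs. In every library 29628 genes were at 0.

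Choices made before the data were examined were the test, the filter, the gene lists and the alternatives, except those named as added. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend and without a block, on log2(value + 1), which understates changes of low genes. Genes needed a normalized count of at least 10 in at least 3 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment over 13527 genes and a threshold of 0.05. Because the values were normalized, edgeR 4.0.16 (quasi-likelihood) and DESeq2 were run on the recovered reads as alternatives. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists with at least 4 tested members, and again with an estimated correlation and with fry. List names cover the CD47-SIRP axis, efferocytosis, Fc, complement and scavenger receptors, LXR targets, cholesterol biosynthesis, NRF2, NF-kB, interferon, alternative activation, MHC class I and II, macrophage identity, cell cycle, lysosome, osteoclast, glycolysis, oxidative phosphorylation, matrix, immediate early and stress genes, mitochondrially encoded genes, Xist with Y-linked genes, and markers of neutrophils, monocytes, dendritic cells, fibroblasts, B cells, T and NK cells, mast cells, erythroid cells and megakaryocytes.

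Named genes were Sirpa; the 12 largest positive and 12 largest negative changes past the threshold with a mean of at least 100, a symbol that is not a predicted model and groups that do not overlap, of which only Sirpa qualified; up to 4 members of each tested list with the smallest p; and the 5 genes with the highest mean. Members that did not pass are given as values. Alternatives were the pseudocount (0.1 and 10), no filter and a minimum of 50, rescaling by TMM, median or quantiles, no trend, array weights, the replicate number as a block, stricter thresholds and leaving out each library. Added after seeing the data were a fit without the third library of each group, a fit with 1 surrogate variable (sva 3.50.0) and the CD47-SIRP list without Sirpa.

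The scripts were tested on simulated counts, drawn for each gene and library independently from the real means, library sizes and each gene's estimated dispersion, with 200 changed genes. Of these, limma recovered 32.3% of genes changed 1.5-fold, 78.8% changed 2-fold and 93.8% changed 4-fold among 13520 genes run. Of its 145 calls, 11 were unchanged genes. Replicates were compared before averaging, and no pair agreed within sampling noise (chi-square per degree of freedom 13.4 or more). Depth ran from 28653015 to 67446846 assigned reads per library. Depth sets counting error only, and the spread between libraries sets the precision of all but low genes.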

Results

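The series measured poly(A) RNA of mouse bone marrow derived macrophages, which are cells grown out of bone marrow in the presence of colony-stimulating factor 1. Cultures were kept for 7 days in medium with 30% L929 cell-conditioned medium, and the mice, C57BL/6 by the labels, were 8 weeks old. There were 3 libraries from SIRPa knockout (KO) cells and 3 from wild-type (WT) cells, all untreated. Reads assigned to genes, recovered from the deposited normalized counts, numbered 28653015, 31401080 and 29643857 in KO replicates 1, 2 and 3, and 34102444, 37307975 and 67446846 in WT replicates 1, 2 and 3. WT replicate 3 was therefore the deepest. The labels do not say whether replicates came from separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical. The comparison of KO with WT asks which transcripts differ in resting macrophages that lack SIRPa, the inhibitory receptor for CD47 on myeloid cells.

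Sirpa, the targeted gene, was 51.3-fold lower in the KO libraries. Its normalized count was 2101.8, 2112.1 and 2010.4 in the KO libraries against 110498, 114095 and 94737 in the WT libraries. The mean was 2074.8 ± 56.0 (SD, n = 3) in KO and 106443 ± 10297 (SD, n = 3) in WT, so that the KO level was 1.95% of the WT level. On the log2(value + 1) scale the gene fell by 5.68 (SE 0.11, 95% interval -5.92 to -5.44), with an adjusted p of 6.45e-10 by limma. Sirpa (ENSMUSG00000037902) lies on chromosome 2 of GRCm38 from 129592835 to 129632228 on the plus strand. It ranked between 22 and 24 among all genes of the WT libraries and between 3500 and 3691 in the KO libraries. The libraries thus matched their labels. Which exons were deleted is not given in the sources used here, and reads along the gene were not analysed here, so the remaining 1668 to 1844 KO reads per library were not placed within it.

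**Figure D1:**
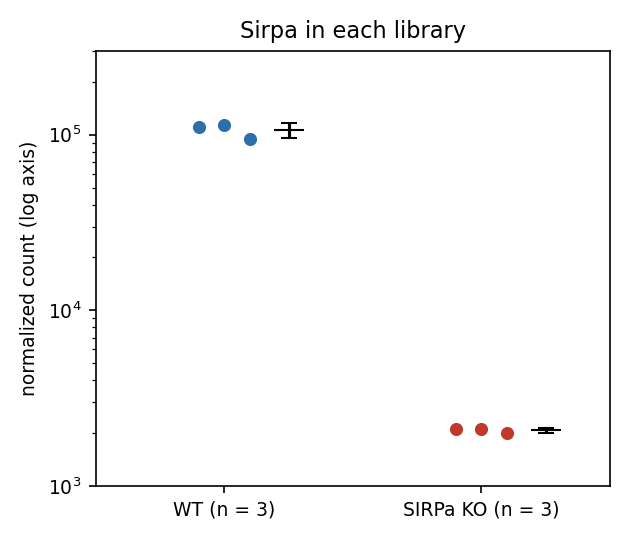
Normalized count of Sirpa (log axis) in each of the 3 WT and 3 KO libraries; points are libraries, and the horizontal mark with its bar is the mean ± SD of the group. The KO libraries sit between 2010.4 and 2112.1, all below the WT libraries at 94737 to 114095.

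No other gene passed the test. Of 13527 genes tested with limma, 0 were higher and 1, Sirpa, was lower in KO at an adjusted p under 0.05, and the smallest adjusted p of the remaining genes was 0.9998. At an unadjusted p under 0.05 there were 205 genes, 93 higher and 112 lower in KO, where chance alone gives 676.4. This count was 643 without KO replicate 2 and 673 without WT replicate 2, but 116 to 232 without each of the other libraries. The shortfall thus depends on single libraries and does not measure how alike the groups are. On the recovered reads, edgeR's quasi-likelihood test called 1 of 13311 genes (207 at an unadjusted p under 0.05), and DESeq2 called 1 of 24603 (217 at an unadjusted p under 0.05). In the authors' deposited table, likewise, 1 gene of 24603 had an adjusted p under 0.05. The groups did not overlap for 631 genes, 4.66% of those tested, where chance gives 10% for 3 against 3.

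The intervals limit how large a missed difference can be. Among 10338 genes other than Sirpa with a mean normalized count of at least 100, the 95% interval of the fold change lay within 2-fold in either direction for 98.4%, and within 1.5-fold for 88.5%. Over all 13526 tested genes other than Sirpa these shares were 87.7% and 69.1%. In simulated data with the real library sizes and each gene's estimated dispersion, limma recovered 92.5% of genes changed 2-fold and 40.4% of those changed 1.5-fold, at a mean of at least 100 and among 13520 genes run. The simulated libraries were drawn independently. Of their unchanged genes 4.95% had a p under 0.05, against 205 of 13527 genes in the real libraries. In the simulation limma called 145 genes, against 1 in the real libraries. The Benjamini-Hochberg cut-off on the unadjusted p is stricter when fewer genes pass. The recovery thus need not be as high in the real libraries, and recovery of a single changed gene was not simulated.

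**Figure D2:**
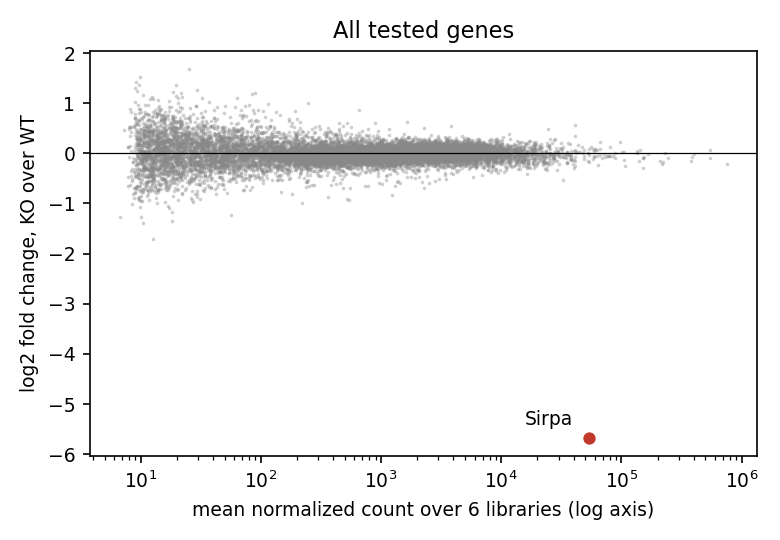
Log2 fold change of KO over WT against the mean normalized count over the 6 libraries (log axis) for each of the 13527 tested genes; grey points did not pass the test and the red point did. Sirpa, at -5.68, stands alone below the cloud of other genes.

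Macrophage transcripts were abundant in both groups. Values from here on are mean normalized counts ± SD of 3 libraries per group. In all 25 lists tested, Sirpa was the only member that passed, also when adjusted over the list alone. The highest means belonged to Lyz2 (lysozyme), Gpnmb, Fth1 (ferritin heavy chain), Apoe (apolipoprotein E) and Ctsb (cathepsin B). Lyz2 stood at 697991 ± 68144 normalized counts in KO and 808023 ± 124186 in WT, and Apoe at 396786 ± 50909.7 and 401735 ± 64192 (SD, n = 3 each). Of 18 macrophage identity genes, 0 rose, 0 fell and 18 did not pass, with a median log2 fold change of -0.08 (camera adjusted p = 0.0732). Cd14, a co-receptor for lipopolysaccharide, was 12259 ± 1891 in KO and 15175 ± 330 in WT (log2 fold change -0.32, unadjusted p = 0.0254). Maf stood at 30785 ± 6358 and 25196 ± 3710.4. Of 24 lysosome genes (median -0.06, adjusted p = 0.125), 14 osteoclast and fusion genes (-0.06, 0.408), 19 matrix remodelling genes (-0.05, 0.48) and 24 NRF2 targets (-0.07, 0.125), 0 rose and 0 fell. At the preset correlation macrophage identity (adjusted p = 0.00341, median -0.09), lysosome (0.00248, -0.08), osteoclast (0.0413, -0.11) and matrix genes (3.36e-04, -0.14) were called lower without WT replicate 3, macrophage identity also with the replicate block (0.0320), lysosome genes without KO replicate 2 (0.0227, -0.10) and NRF2 targets without KO replicate 1 (0.00649, -0.09). With an estimated correlation these had adjusted p = 0.281 or more. Spp1, which encodes osteopontin, was 136176 ± 7847 in KO and 167375 ± 29259.6 in WT.

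Genes of the CD47 and SIRP signalling route other than Sirpa did not pass. Of 14 members, 1 fell and 13 did not pass, both over all genes and adjusted over the list alone. Tyrobp, the adaptor for activating receptors such as SIRPb1, was 22718 ± 5078 normalized counts in KO and 26308 ± 3387 in WT (log2 fold change -0.23, SE 0.17). Sirpb1b, a paralog of Sirpa, was 214 ± 27.7 and 242 ± 7.80; reads of the SIRP family may be split between near-identical copies. The list was called lower with a preset correlation of 0.01 (adjusted p = 0.0111) and by fry (adjusted p = 0.0102), but with an estimated correlation its adjusted p was 0.416. The fry test was not run without Sirpa, so its call may rest on the targeted gene. That preset call was lost without Sirpa (adjusted p = 0.565, median -0.06), and also without KO replicate 3 (just over the 0.05 threshold, median -0.06), WT replicate 1 (0.0546, -0.05) or WT replicate 2 (0.178, -0.06). Without WT replicate 3 the call held and the median was -0.045.

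Receptors for engulfment, the process that SIRPa restrains, had values in both directions. Of 16 efferocytosis genes, 0 rose, 0 fell and 16 did not pass, with 12 above and 4 below WT (median 0.04, camera adjusted p = 0.102). At the preset correlation the list was called higher without KO replicate 3 (adjusted p = 0.0402, median 0.11), without WT replicate 2 (0.0187, 0.12), with the replicate block (0.0414, 0.04) and with 1 surrogate variable (0.00955, 0.10), and with an estimated correlation these had adjusted p = 0.532 or more. Mertk, a receptor for apoptotic cells, was 2323 ± 306 in KO and 1944 ± 279 in WT (log2 fold change 0.26, SE 0.14), and Dock1 was 3068 ± 364 and 2561 ± 347. Mertk lies on chromosome 2 from 128698956 to 128802894, within 10 Mb of Sirpa. A difference linked to the targeted locus thus cannot be told apart for Mertk. Of 21 Fc, complement and scavenger receptors, 0 rose and 0 fell (median -0.02, adjusted p = 0.333). Without WT replicate 3 this list was called lower (adjusted p = 0.00625, median -0.07), and with an estimated correlation the adjusted p was then 0.287. Mrc1, the mannose receptor, was 28075 ± 2901 in KO and 20586 ± 5495 in WT (log2 fold change 0.48, unadjusted p = 0.0271). Fcgr1 was 7225 ± 838 and 8444 ± 811, and Cd5l, a secreted scavenger protein, was 2042 ± 208 and 2590 ± 173.

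Lipid genes stood slightly below WT as groups, with no member past the test. All 24 cholesterol biosynthesis genes were below WT in the mean (median log2 fold change -0.15, camera adjusted p = 9.39e-07 with the preset correlation, adjusted p = 0.416 with an estimated correlation). Without KO replicate 3 this median was -0.096. Insig1, which retains the sterol sensor in the endoplasmic reticulum, was 3636 ± 64.3 in KO and 4416 ± 454 in WT (log2 fold change -0.28, unadjusted p = 0.0263). Of 17 genes of cholesterol efflux and LXR, the oxysterol receptor, 0 rose, 0 fell and 17 did not pass, with 13 below WT (median -0.16, adjusted p = 1.53e-04, and adjusted p = 0.416 with an estimated correlation). Scd1, a desaturase of fatty acids, was 147 ± 44.9 and 294 ± 86.2 (log2 fold change -0.99, SE 0.27, unadjusted p = 0.00399), and Abcg1, a cholesterol exporter, was 2931 ± 270 and 3850 ± 575 (-0.39). Without WT replicate 2 the LXR list was not called (adjusted p = 0.289, median -0.10).

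Interferon-stimulated genes showed the lowest list median with all libraries. All 30 were below WT in the mean, 0 passed alone, and the median log2 fold change was -0.37 (camera adjusted p = 8.37e-19 with the preset correlation, adjusted p = 0.416 with an estimated correlation of 0.69). Ifit3 was 1755 ± 552 in KO and 2765 ± 599 in WT (-0.69, unadjusted p = 0.0133), and Isg15, a ubiquitin-like protein, was 580 ± 195 and 901 ± 255 (-0.65). The libraries differed within groups: the list's median deviation was -0.65, 0.03 and -0.01 in the KO libraries and 0.00, 0.21 and 0.40 in the WT libraries. Without KO replicate 1 the median was -0.21. Lists of immediate early (-0.33), NF-kB (-0.24) and MHC class II genes (-0.22) were then lower. Immediate early genes were also lower without KO replicate 2 (-0.54 against -0.49). Without WT replicate 3 immediate early (-0.57) and NF-kB genes (-0.31) were lower than interferon-stimulated genes (-0.29). Genes of MHC class I presentation (13 of 14 below WT, median -0.18, adjusted p = 3.79e-05) and class II presentation (8 of 10, -0.22, 0.00203) had adjusted p = 0.416 each with an estimated correlation. The class I median was -0.29 without KO replicate 2, -0.11 without KO replicate 1 and -0.11 without WT replicate 3. H2-T23 was 5945 ± 1337 in KO and 7972 ± 838 in WT. Without KO replicate 3 the class II list was not called (adjusted p = 0.118, median -0.11).

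Inflammatory and activation genes likewise had no member past the test. Of 24 NF-kB genes, 21 were below WT (median -0.22, adjusted p = 1.96e-06, and adjusted p = 0.416 with an estimated correlation). Without KO replicate 2 this median was -0.39. Ccl3, a chemokine, was 1760 ± 165 in KO and 2208 ± 196 in WT (-0.33), and Saa3, near the filter on low values, was 9.13 ± 2.06 and 27.1 ± 15.4. Of 16 alternative activation genes 12 were below WT (median -0.14, adjusted p = 0.0375, and adjusted p = 0.416 with an estimated correlation), with Clec10a at 123 ± 18.0 and 179 ± 30.6. Mrc1, given above and also a member, was among the 4 above WT (log2 fold change 0.48). The list's call was lost without KO replicate 3 (adjusted p = 0.445, median -0.07), WT replicate 1 (0.0614, -0.15) or WT replicate 2 (0.491, -0.05). Without KO replicate 2 its median was -0.21.

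Metabolic, stress and cell cycle groups varied between single libraries. Oxidative phosphorylation genes were below WT for 24 of 25 members (median -0.11, adjusted p = 4.69e-04, and adjusted p = 0.669 with an estimated correlation), and Cox5a was 2539 ± 348 in KO and 2929 ± 551 in WT. That call was lost without KO replicate 3 (adjusted p = 0.575, median -0.03) or WT replicate 3 (0.354, -0.02), and the median was -0.18 without KO replicate 2 and -0.21 without WT replicate 2. Glycolysis and hypoxia genes had a median of -0.10 over 23 tested entries of 22 gene symbols (adjusted p = 0.0284, and adjusted p = 0.56 with an estimated correlation), with Vegfa at 2235 ± 690 and 3403 ± 1385. Without KO replicate 3 their median was 0.04 (adjusted p = 0.786), and the call was lost without WT replicate 1 (0.13, median -0.08) or WT replicate 2 (0.217, -0.08). Of 20 immediate early and stress genes 19 were below WT (median -0.31, adjusted p = 9.21e-05, and adjusted p = 0.56 with an estimated correlation). Their median deviation was -0.60 in KO replicate 3, and the call was lost without that library (adjusted p = 0.575, median -0.03) or WT replicate 2 (0.125, -0.13). This median was -0.54 without KO replicate 2, -0.11 without WT replicate 1 and -0.57 without WT replicate 3. Of 28 cell cycle genes, 0 rose and 0 fell (median 0.02, adjusted p = 0.0669), and their median deviation was 0.52 in WT replicate 3. The list was called higher without that library (adjusted p = 1.04e-18, median 0.24) or without KO replicate 3 (0.00521, 0.04) at the preset correlation. With an estimated correlation the adjusted p = 0.281 and 0.844 for these, and adjusted p = 0.687 with all libraries. Mcm4, part of the replicative helicase, was 5354 ± 448 in KO and 4473 ± 313 in WT (0.26).

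**Figure D3:**
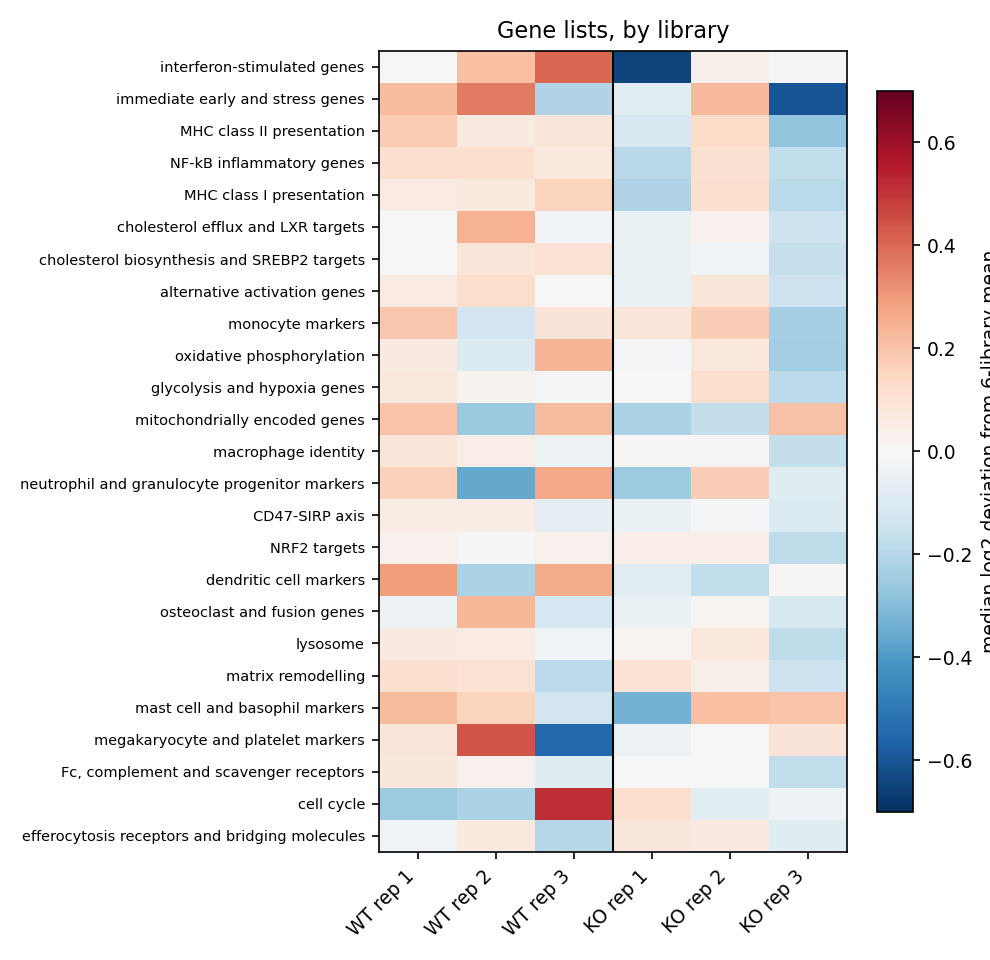
Median log2 deviation of each tested gene list (25 lists, vertical axis) from the mean of the 6 libraries in each library (horizontal axis); red is above and blue below that mean. The darkest cells belong to single libraries, such as interferon-stimulated genes in KO replicate 1 at -0.65 and immediate early genes in KO replicate 3 at -0.60.

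Markers of other cell types were low or did not pass. Of 11 neutrophil and progenitor markers (median -0.08, adjusted p = 0.19), 10 monocyte markers (-0.14, 0.752) and 8 dendritic cell markers (-0.07, 0.199), 0 rose and 0 fell. Without WT replicate 2 the neutrophil (adjusted p = 0.0230, median -0.24) and dendritic cell markers (0.0336, -0.24) were called lower at the preset correlation, with adjusted p = 0.647 each with an estimated correlation. Ccr2, the receptor that brings monocytes out of bone marrow, was 7883 ± 827 in KO and 9844 ± 872 in WT, while F13a1 was 4480 ± 755 and 3219 ± 1224. Mast cell and basophil markers (4 tested, median -0.04, mean 0.03, test direction down, adjusted p = 0.976) and megakaryocyte markers (5 tested, median -0.03, mean 0.03, test direction up, adjusted p = 0.752) gave signs that differ between median and mean. Lists of fibroblast, B cell, T and NK cell and erythroid markers had fewer than 4 members past the filter and were not tested. Their highest member had a mean over the 6 libraries of 20.2, 5828, 18.3 and 3.83 normalized counts, in that order. The B cell value was Ighm, the heavy chain of immunoglobulin M, and Cd79b, of the B cell receptor, had a mean of 53.3 and Cd79a of 0.887; these were named after their values were seen. Of the mitochondrially encoded genes 12 of 14 were below WT (median -0.10, adjusted p = 0.0725). They were called lower at the preset correlation without KO replicate 3 (adjusted p = 1.12e-06, median -0.24), without WT replicate 2 (9.88e-04, -0.26) and with the replicate block (0.0498, -0.10), with adjusted p = 0.643 or more with an estimated correlation, and mt-Co1 was 354925 ± 9092 in KO and 398715 ± 42834 in WT. Xist was present and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 in all 6 libraries.

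Genes near Sirpa were compared with the rest of the genome, because a targeted locus can carry linked differences. Within 10 Mb on each side, 4 of 164 genes other than Sirpa had an unadjusted p under 0.05, 2.44% against 1.48% elsewhere (Fisher's exact test, two-sided, p = 0.314). Within 5 Mb there were 2 of 103 (p = 0.668, same exact test) and within 20 Mb 4 of 248 (p = 0.789, same exact test), and none of these genes passed the adjusted threshold.

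**Figure D4:**
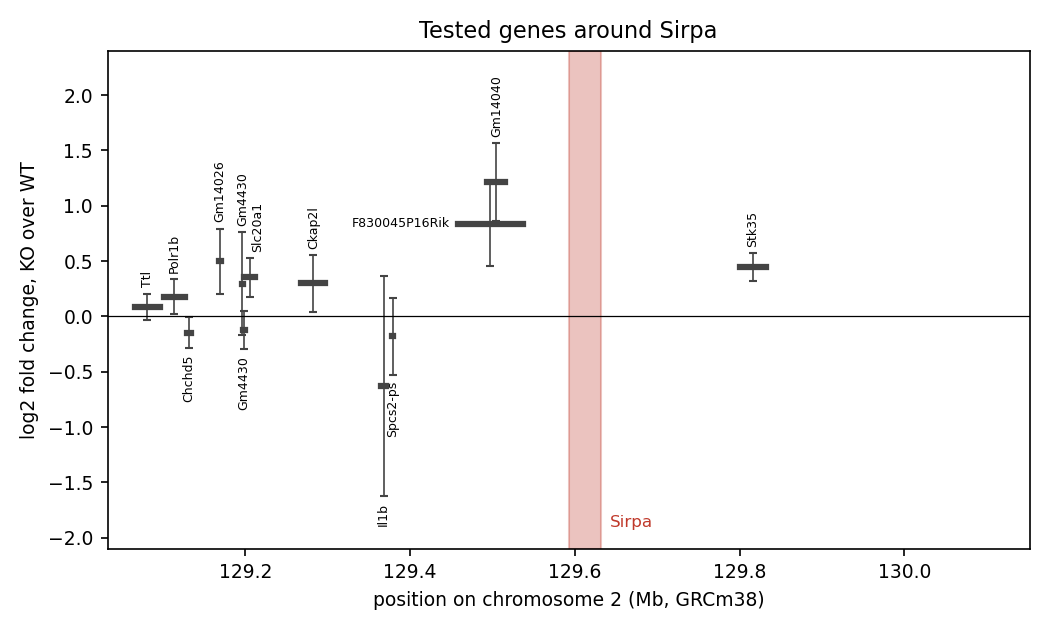
Log2 fold change of KO over WT (vertical axis) for the 13 tested genes within 0.5 Mb of Sirpa, at their positions on chromosome 2 in Mb (GRCm38); horizontal bars span each gene, vertical bars are ± SE and the shaded band is Sirpa. Stk35 at 0.45 and Gm14040 at 1.21 lie above 0, and neither passed the adjusted threshold.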

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

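Sirpa was the only gene called under every alternative but array weights, and its log2 fold change ran from -5.76 to -5.62 when each library was left out in turn. Leaving out libraries gave 0 genes higher and 1 lower each time. Array weights called 1685 genes higher and 1813 lower. They gave KO replicate 1 a weight of 6.61 and WT replicate 1 a weight of 7.10 against 0.258 to 0.543 for the other libraries, and the estimation stopped before it converged, so that fit compared little more than 1 library per group. Under these weights Kit had a log2 fold change of -0.56 against 0.04. Of 2026 values of the 102 named genes other than Sirpa, 1966 stayed short of the threshold, whatever their direction. The others, all under array weights, passed it, 59 in the direction of the main test and 1 in the opposite direction. Rescaling moved the median log2 fold change of all genes to 0.013 at most.

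List calls depended on the test. With an estimated correlation all 11 preset calls were lost at unchanged medians. With fry all were lost but that of the CD47-SIRP axis, a list tested there with Sirpa in it. With an estimated correlation 0 lists were called under each of the alternatives it was run with, array weights and left-out libraries included. Those medians were -0.071 for the CD47-SIRP axis, -0.16 for LXR targets, -0.15 for cholesterol biosynthesis, -0.22 for NF-kB genes, -0.37 for interferon-stimulated genes, -0.14 for alternative activation, -0.22 for MHC class II, -0.18 for MHC class I, -0.10 for glycolysis, -0.11 for oxidative phosphorylation and -0.31 for immediate early genes. The CD47-SIRP axis lost its call without Sirpa (-0.061), which leaves the called gene out, and under quantile normalization (-0.053), as did glycolysis (-0.10). Alternative activation lost it without a filter (-0.16), and cell cycle genes gained one with the stricter filter (0.023). Under array weights calls were lost for cholesterol biosynthesis (-0.071), alternative activation (-0.063) and glycolysis (-0.045), and gained for cell cycle (0.28), neutrophil markers (-0.29) and mitochondrially encoded genes (-0.42), while NF-kB (-0.36) and interferon-stimulated genes (-0.58) kept theirs with larger medians.

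Among fits added after seeing the data, 1 surrogate variable ended the calls of the CD47-SIRP axis (-0.072), alternative activation (-0.060), glycolysis (-0.013) and immediate early genes (-0.070), and added efferocytosis (0.10) and mitochondrially encoded genes (-0.21), while LXR targets (-0.099) and MHC class II (-0.13) kept theirs with smaller medians. Without the third library of each group the median of oxidative phosphorylation reversed to 0.051 and that of glycolysis was 0.014, both without a call, while macrophage identity (-0.050), cell cycle (0.25) and mitochondrially encoded genes (-0.19) were called, and medians moved to -0.098 for cholesterol biosynthesis, -0.11 for MHC class I and -0.097 for MHC class II with their calls kept. The cause was not tested in any of these cases.

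With each library left out in turn, NF-kB genes (-0.39 to -0.15), MHC class I (-0.29 to -0.11), cholesterol biosynthesis (-0.19 to -0.096) and interferon-stimulated genes (-0.51 to -0.21) kept their call. These lists changed it at least once, with medians from -0.063 to -0.045 for the CD47-SIRP axis, 0.015 to 0.12 for efferocytosis, -0.071 to 0.023 for Fc and scavenger receptors, -0.17 to -0.10 for LXR targets, -0.12 to 0.0057 for NRF2 targets, -0.21 to -0.047 for alternative activation and -0.28 to -0.11 for MHC class II. They ran from -0.099 to -0.035 for macrophage identity, -0.098 to 0.24 for cell cycle, -0.10 to 0.024 for lysosome, -0.11 to 0.021 for osteoclast genes, -0.13 to 0.042 for glycolysis, -0.21 to -0.024 for oxidative phosphorylation and -0.14 to 0.016 for matrix remodelling. For immediate early genes they ran from -0.57 to -0.028, for neutrophil markers from -0.28 to 0.054, for dendritic cell markers from -0.24 to 0.019 and for mitochondrially encoded genes from -0.26 to 0.0043. Lists not called with all libraries were called without KO replicate 1 (NRF2), KO replicate 2 (lysosome), KO replicate 3 (efferocytosis, cell cycle, mitochondrial), WT replicate 2 (efferocytosis, neutrophil, dendritic, mitochondrial) or WT replicate 3 (Fc receptors, macrophage identity, cell cycle, lysosome, osteoclast, matrix). Depth limits mainly genes with few reads.

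The replicate numbers were not used as pairs, a choice made beforehand because the labels give no shared animal, litter or day for a number. Residuals of same-numbered libraries correlated at 0.01, 0.31 and 0.13, and those of other pairs at -0.26 to 0.15. The first principal component (37.7% of variance) placed the libraries numbered 2 at -19.6 and -22.6 and those numbered 1 at -1.26 and -0.27. Those numbered 3 stood at 37.2 and 6.51. A factor shared by number is thus unresolved. On the log2 scale the libraries numbered 1 correlated best with each other (0.9934), as did those numbered 2 (0.9944). KO replicate 3 (0.9887) and WT replicate 3 (0.9904) correlated best with WT replicate 1. With the replicate block 0 genes were higher and 1 was lower, with 327 at an unadjusted p under 0.05, and 14 lists were called, adding efferocytosis (0.037), macrophage identity (-0.078) and mitochondrially encoded genes (-0.10).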

Other observations

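The tests of the interferon list, of the genes beside Sirpa and of the neighbour sizes were chosen after the values they use were seen. The tests on ribosomal protein genes, on receptor genes and on other splits of the libraries for counts of genes and lists were written before. For ribosomal protein and receptor genes the spread between libraries was added to the rule after the results were seen. That addition did not change the reading for ribosomal protein genes. The genes named in the next sentences, and all genes beside Sirpa, fall outside the rule for named genes and were chosen after their values were seen. Folr2, a folate receptor of resident macrophages, had the smallest p after Sirpa. It stood at 4890 ± 300.2 normalized counts in KO and 6808 ± 405 in WT (log2 fold change -0.48, SE 0.10, unadjusted p = 7.80e-04, limma adjusted p = 0.9998), lower in 3 of 3 KO libraries. Acss2, an acetyl-CoA synthetase, was 215 ± 2.31 and 335 ± 55.9 (-0.63), and Slc15a2, a peptide transporter, was 122 ± 18.6 and 55.5 ± 23.2 (1.20). Nnt, which C57BL/6J mice carry with a deletion, stood between 4.82 and 26.5 in all 6 libraries.

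Of the 10 splits of the 6 libraries into 3 and 3, 2 called as many genes as the real split, which is itself counted. The real split called 1, Sirpa, and the highest other called 1, Camk2b, a gene chosen after its values were seen. With the preset correlation 3 of the 10 splits, again counting the real one, called at least as many lists. The real split called 11 and the highest other 15. With 10 splits a share under 0.05 cannot be reached. The split of KO replicates 1 and 2 with WT replicate 2 from the rest had 1605 genes at an unadjusted p under 0.05, where the real split had 205 and the other 8 had 145 to 1305; after adjustment that split called 0.

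Genes beside Sirpa stood above WT in 9 of the 13 entries tested within 0.5 Mb, which hold Gm4430 more than once. The median log2 fold change of all tested genes was -0.006, and the count of 9 was not tested against it. Stk35 was 1088 ± 103 in KO and 798 ± 74.4 in WT (log2 fold change 0.45, unadjusted p = 0.00460), and Gm14040, inside F830045P16Rik on the same strand so that their reads may overlap, was 26.4 ± 6.13 and 10.9 ± 3.18; neither passed the adjusted threshold. Few genes had neighbours with a mean t as high: 0.0148% of 13513 with 13 nearest neighbours, a count that includes Sirpa itself. With 3, 5, 10 or 20 neighbours, sizes tried after that first result, the share was 0.00740% to 0.0444%. At 3, 10 and 20 this was Sirpa alone. The test was chosen after the pattern was seen and counts Gm14040 and F830045P16Rik, whose reads may overlap, as separate neighbours. It thus does not decide whether such clusters arise anywhere. Reads lost with Sirpa would lower its neighbours in KO, opposite to the pattern, so no test of them as its cause is used. Their median log2 fold change of 0.29 (SE 0.16) and mean t of 1.05 (SD 0.32 over all sets of 13 neighbours) restate the pattern and decide nothing. A linked interval over megabases stays open, with 1.32% of genes 0.5 to 10 Mb away at an unadjusted p under 0.05 (exact 95% interval 0.161% to 4.70%) against 1.48% elsewhere. A local effect of the altered allele on neighbouring transcription may be a candidate explanation, untested here.

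KO replicate 3 held more processed pseudogene reads, 0.316% of its reads against 0.162% to 0.228% in the other 5 libraries. Ribosomal protein pseudogenes deviated by 1.34 (median log2, 60 genes) in that library. Shared reads from more abundant parent genes are argued against, since the 82 protein-coding Rpl and Rps genes deviated by -0.31 there, and by -0.21 to 0.45 in the other libraries. That value covers the abundance of the parents only. How reads were assigned between parents and pseudogenes in that library was not examined. Genomic DNA stays open: reads in olfactory and vomeronasal receptor genes were 1.38 times those of the other 5 libraries (exact 95% interval 1.23 to 1.55) against 1.597 times for processed pseudogenes. The bound set beforehand, which this ratio met, covered counting error only; with the spread between libraries, added after the result was seen, the receptor ratio reaches 1.58 and the pseudogene ratio 1.28, so these ranges overlap; no biological explanation was tested.

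Interferon-stimulated genes had a median below WT that was called as a list only at the preset correlation (adjusted p = 0.416 with an estimated correlation, and 0.571 by fry), and KO replicate 1 held the lowest values. Whether that library alone is the cause stays open. Without it the list's median was -0.21 against -0.37 with it, but the members are correlated (0.69), so they are not independent, and between libraries the remaining KO medians of 0.03 and -0.01 overlapped the WT medians of 0.00, 0.21 and 0.40 (difference of their means -0.19, SE 0.15). The bound written for this test covered the spread over genes only and was met; the spread between libraries was added after the result was seen. Among the 9 other splits, 2 gave a median difference as large, up to 0.42 against 0.37. Both kept KO replicate 1 with another KO library and set WT replicates 2 and 3 on the other side. They thus stay close to the genotype split and do not decide whether the difference follows genotype. Genotype, the single library and a difference between libraries that does not follow genotype are all open for this list.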
